A study of Drosophila melanogaster with 6 samples.

How the data were processed

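The data were 6 two-colour microarrays of RNA recovered by immunoprecipitation (IP) from ovaries of newly eclosed Drosophila melanogaster females. On each array an IP with an antibody against Orb, a germline RNA-binding protein of the CPEB family, was hybridised together with a mock IP made with commercial mouse immunoglobulins. The Orb antibody was 6H4, per the labels. All 6 arrays formed 1 group, and the replicate numbers 1 to 6 came from the sample titles. The Orb IP was labelled with Cy3 on replicates 1, 3 and 5 and with Cy5 on replicates 2, 4 and 6, and the mock IP carried the other dye. The labels do not say whether the arrays came from separate extracts, so the p-values measure only the spread between these samples, which may be technical.

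Per the labels' protocols, RNA was labelled with an amino allyl amplification kit. Per the file headers, the deposited intensity values are spot volumes (level times area) in Cy3 and Cy5, with a local background for each spot and channel. Another deposited intensity column held volume minus background, set to 0 where this was negative. The authors' deposited ratio column held Cy3 over Cy5 on a log10 scale, computed from normalized volumes, with placeholder values where a channel was 0. The normalization behind that column, the scanner software and the array layout are not given in the sources used here. The values of spot flags were 0 or 1, with no criterion stated.

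The files name each of the 15744 spots only by its block, row and column, in 24 blocks of 656 spots. They do not pair these positions with genes, and the gene table used here lists no array positions. The planned ratios of orb and Atg12, the autophagy list and the other gene lists (23 lists in all, fixed in advance) were therefore not computed, and results are given by spot. A spot is written here as block, row and column, so that B7_R6_C9 is block 7, row 6, column 9. No more than 2 spots that were higher in the Orb IP and 2 that were higher in the mock IP are named.

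A spot counted as above background in a channel where its volume exceeded the local background by more than 2 SD. The files give no SD of the background, so the scaled median absolute deviation of that array's local backgrounds in that channel was used. At 13 positions in the first row of the blocks, at least 20 of the 24 blocks were above background in a channel on all 6 arrays. These 312 spots were treated as repeated control prints and left out of the test and of the loess fit. That rule was set after the data had been seen, since the files mark no controls, and after a stricter one requiring both channels (192 spots) had been run; both counts are reported below. Flagged spots (0 to 73 per array) were also left out.

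Ratios were computed in R 4.3.3 with limma 3.58.1. Background was corrected with normexp and an offset of 50, ratios were normalized by loess (span 0.3) within each array, and no step was applied between arrays. An offset of 50 is large beside median local backgrounds of 0.706 to 14.5 units, so it draws the ratios of most spots towards 0. Spots above background in at least 1 channel on at least 3 of the 6 arrays were tested. The limma model held a term for Orb over mock, coded by the dye orientation, and a spot-specific dye term. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. For single values per array, an exact sign-flip test over the 6 arrays was used, which cannot give a p under 0.03125. Correlations between arrays are across spots, which are not independent replicates.

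The naming rule fixed in advance took the 12 largest positive and 8 largest negative log2 ratios. These came from items past the threshold with the same sign on all 6 arrays and a mean brightness at or above the median of those tested. The first 2 of the 12 Orb-higher spots are named. No mock-higher spot met the rule, and the mock-higher spots named were chosen after their values were seen.

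The steps were tested on simulated data. Simulated arrays gave each spot 1 signal, its median over the 12 channels, in both IPs. To this were added the real local backgrounds, each channel's own gain and noise, and a spread of 0.25 (log2) per spot and array. The noise of a channel was taken from the spots whose volume lay below their background. In 20 simulated sets with no difference between the IPs, a median of 3477 spots were tested, and the planned fit called a median of 677 of them. The planned fit was thus not calibrated on these simulated arrays, and its calls are given with that count beside them. The spread was a set value and no spot-specific dye bias was simulated, so that count does not measure the rate of false calls on the real arrays. On the same sets median centring called 0. In a further set with 200 spots changed in the comparison of Orb IP over mock IP (3516 spots tested), the planned fit recovered 28 of 100 changed by a log2 of 1, of which 25 had the right sign, and 64 of 100 changed by a log2 of 3, with 644 unchanged spots called. Median centring recovered 4 and 21, with 1 unchanged spot called.

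The settings varied, chosen before the data were examined, were the background correction, the normalization within and between arrays, the filter on dim spots, the dye term, array weights, the independence of consecutive arrays, each dye orientation alone, the moderation, a minimum size, an unmoderated t-test and leaving out each array in turn. Settings added after seeing the data were an offset of 1, keeping the repeated prints or setting them by both channels, keeping flagged spots, loess fitted on the tested spots only, the same loess without background correction, the authors' deposited ratio column and 2 stricter limits for detection. The number of arrays, 6, limits the precision.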

Results

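Orb immunoprecipitates and mock immunoprecipitates from ovaries of newly eclosed Drosophila females were compared on 6 two-colour arrays, 3 with the Orb IP in Cy3 and 3 with it in Cy5. Orb is a germline RNA-binding protein, and the series concerns its control of translation in relation to autophagy. The comparison asks which RNAs were recovered with Orb above the level of the mock IP. Genes could not be assigned to spots, so the spots themselves were counted and compared. Of 15432 spots outside the repeated prints, 6613 (42.9%) were above background in neither IP on any array.

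At 2 SD over background, the number of spots detected followed the dye more closely than the IP. In the Orb IP, 7.80%, 11.4% and 8.03% of the spots were above background on replicates 1, 3 and 5, where Orb was in Cy3. On replicates 2, 4 and 6, where Orb was in Cy5, the shares were 15.8%, 29.0% and 18.2%. The mock IP ran the other way, with 14.9%, 12.8% and 12.8% on replicates 1, 3 and 5 (Cy5) and 4.51%, 5.74% and 6.56% on replicates 2, 4 and 6 (Cy3). Over all arrays the Orb share was 15.0% ± 8.0 and the mock share 9.56% ± 4.45 (SD, n = 6). The difference of Orb minus mock was 5.48 ± 11.8 percentage points (SD, n = 6; exact sign-flip test, two-sided, p = 0.375). Cy5 exceeded Cy3 on 6 of 6 arrays, by 9.91 ± 7.61 points (SD, n = 6; exact sign-flip test, two-sided, p = 0.03125, the smallest it can give).

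**Figure D1:**
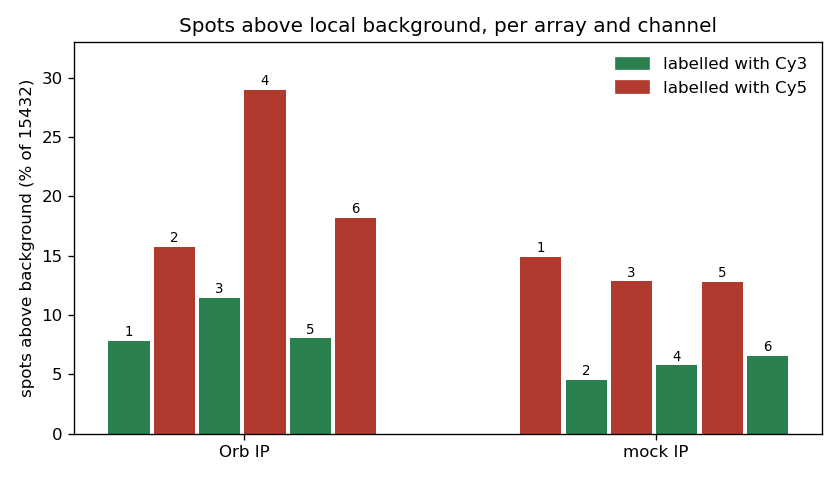
Bars give the percentage of 15432 spots above local background (vertical axis) in the Orb IP and the mock IP, 1 bar per array, numbered by replicate and coloured by dye. Within each IP the Cy5 bars stand above the Cy3 bars, with 15.8% to 29.0% against 7.80% to 11.4% for the Orb IP.

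The local backgrounds differed between the 2 orientations. With Orb in Cy5, the median background was 0.872 ± 0.207 units in the Orb channel and 13.3 ± 1.0 in the mock channel (SD, n = 3). With Orb in Cy3, it was 3.32 ± 0.139 in the Orb channel and 3.75 ± 0.774 in the mock channel (SD, n = 3). At a fixed limit of 10 units over background, added after the data had been seen, the Orb minus mock difference was -0.086 ± 0.918 points (SD, n = 6; exact sign-flip test, two-sided, p = 0.875). The dye difference was not seen at that limit either: Cy5 exceeded Cy3 on 3 of 6 arrays, by 0.350 ± 0.839 points on average (SD, n = 6; exact sign-flip test, two-sided, p = 0.406).

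Spots that were above background throughout were more numerous in the Orb IP. On all 6 arrays, 435 spots were above background in the Orb IP, 31 in the mock IP and 28 in both. The 2 orientations differed in this. On the 3 arrays with Orb in Cy5, 1422 spots were above background each time in the Orb IP and 33 in the mock IP. On the 3 arrays with Orb in Cy3, 445 spots were so in the Orb IP and 667 in the mock IP. The count of an IP over all 6 arrays cannot exceed its count on the arrays where it was in Cy3. Those counts were 445 for Orb and 33 for mock, on arrays with median Cy3 backgrounds of 3.32 and 13.3 units. The 435 and 31 spots therefore do not compare the IPs alone. Spots above background in one IP on all 3 arrays and in the other on none numbered 983 for Orb and 2 for mock with Orb in Cy5. With Orb in Cy3 they numbered 0 for Orb and 57 for mock.

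A group of 68 spots was above background in the Orb IP on at least 5 arrays and in the mock IP on at most 1. No spot showed the mirror pattern, which would have needed the mock IP above background on arrays where its Cy3 channel was weak. Exchanging the 2 IPs on any of the arrays gave 32 arrangements, and 7 of them, the real one included, gave as many spots. Exchanging the IPs by dye gave 291, and exchanging them on replicate 5 alone gave 209.

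In the ratios of Orb IP over mock IP, 26 of 2370 tested spots passed the threshold (limma, adjusted p under 0.05). Of these, 25 spots were Orb-higher and 1 was mock-higher. At an unadjusted p under 0.05 there were 437 Orb-higher and 15 mock-higher spots. Without the filter on dim spots they numbered 878 and 284 of 15432. The filter admitted spots through the Orb IP alone on replicates 2, 4 and 6, such as the 983 counted above. The direction of the tested spots is therefore not independent of the filter. The 25 Orb-higher spots had log2 ratios of 0.09 to 0.32 with the offset of 50, with a median of 0.15 (1.11-fold). With an offset of 1, the same 25 spots had a median of 0.91. They lay in 17 of the 24 blocks, and 21 of them were Orb-higher on all 6 arrays. The mock IP was above background on 3 or fewer arrays for 21 of the 25. The share among all tested spots is not given here. Few spots at all were above background in the mock IP on replicates 2, 4 and 6 (4.51%, 5.74% and 6.56%), so that count does not set the 25 apart. This fit takes the 6 arrays as separate replicates. With consecutive arrays averaged to 3 values, 0 spots passed (limma), with 355 Orb-higher and 13 mock-higher at an unadjusted p under 0.05. With the same pairs as a random block, 23 passed. The correlation fitted within pairs was -0.076, on Cy5 over Cy3 ratios. There a deviation shared in Orb over mock takes opposite signs on the arrays of a pair.

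The same fit called more spots on simulated arrays that held no difference between the IPs but had the gain and noise of the real channels. Those sets gave a median of 670.5 Orb-higher and 6.0 mock-higher spots among 3477 tested (20 sets). With median centring in place of loess, 0 spots passed on the real arrays (limma), with 152 Orb-higher and 52 mock-higher at an unadjusted p under 0.05. The simulated sets gave a median of 0 calls under that setting, with 154 and 84 at an unadjusted p under 0.05. As shares of the spots tested, the real arrays had 18.4% Orb-higher and 0.633% mock-higher in the planned fit, against 31.4% to 33.5% and 0.486% to 0.936% in the simulated sets. With median centring the real shares were 6.41% and 2.19%, against 3.93% to 5.19% and 2.06% to 2.86%. The Orb-higher share lay above all 20 simulated sets under that setting and below all of them in the planned fit. These shares have unlike denominators, with 2370 spots tested on the real arrays and a median of 3477 in the simulated sets. The Orb-higher counts under median centring (152 and a median of 154) have the same limit, and the simulated spread was a set value. The higher share under that setting therefore cannot show whether Orb-higher spots were in excess. Orb-higher spots did not outnumber mock-higher ones at an unadjusted p under 0.05 on the Orb-in-Cy3 arrays alone (56 to 57) or with loess on the tested spots and no background correction (97 to 152). The simulated sets were not even there either, with medians of 54.5 to 91.0 in the first setting and 181.0 to 146.0 in the second.

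**Figure D2:**
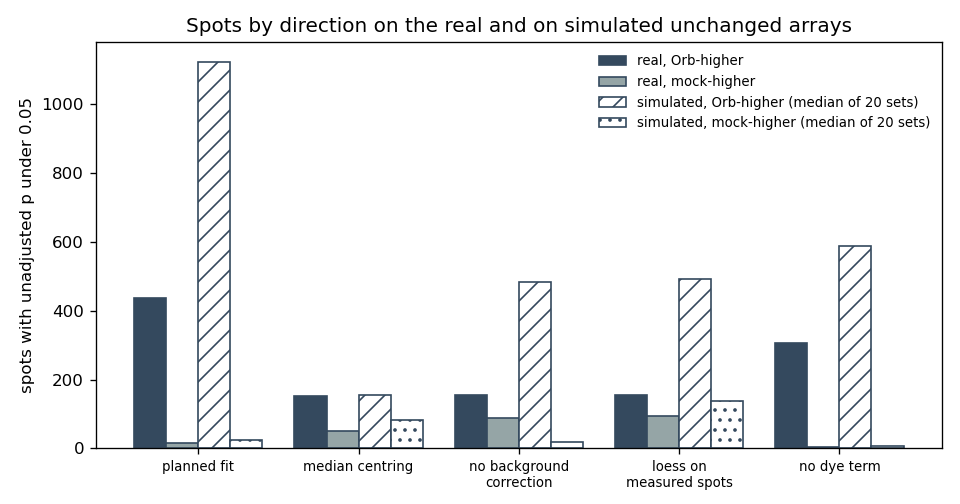
Bars give the number of spots with an unadjusted p under 0.05 (vertical axis) under 5 processing settings (the planned fit, median centring, no background correction, loess on the tested spots, no dye term), for the real arrays (filled; 2370 spots tested) and as the median of 20 simulated sets without a difference between the IPs (hatched or dotted; median of 3477 tested). Orb-higher spots outnumber mock-higher ones under the 5 settings drawn, real and simulated, for example 437 to 15 on the real arrays and 1124 to 24.5 on the simulated ones in the planned fit.

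The spot B11_R13_C20 (block 11, row 13, column 20) had the highest ratio of the 25. Its log2 ratio was 0.32 (SE 0.029; limma, adjusted p = 0.0178), or 1.24-fold, and it was Orb-higher on 6 of 6 arrays. Its signal over background was 57.3 ± 36.9 units in the Orb IP and 19.0 ± 23.8 in the mock IP (SD, n = 6), and the mock IP was above background on 4 of the arrays. With an offset of 1 its log2 ratio was 1.29 (limma, adjusted p = 0.0500263, just past the other side of the threshold). The spot B7_R6_C9 (block 7, row 6, column 9) had a log2 ratio of 0.23 (SE 0.020; limma, adjusted p = 0.0145) and was Orb-higher on 6 of 6 arrays. Its signal was 16.1 ± 7.73 units in the Orb IP and 5.94 ± 10.6 in the mock IP (SD, n = 6), with the mock IP above background on 3 arrays. Its log2 ratios were 0.08, 0.12 and 0.21 with Orb in Cy3 and 0.29, 0.35 and 0.35 with Orb in Cy5. Under median centring neither spot passed the threshold. The log2 ratio was then 0.59 (SE 0.184; limma, adjusted p = 0.543) for B11_R13_C20 and 0.21 (SE 0.083; limma, adjusted p = 0.548) for B7_R6_C9, so under that setting the calls ended with larger standard errors. With loess on the tested spots, chosen after seeing the data, the ratio of B7_R6_C9 was lower, at 0.12 (limma, adjusted p = 0.450), and that of B11_R13_C20 was 0.26 (limma, adjusted p = 0.0631). With consecutive arrays averaged the ratios were as before, with adjusted p = 0.127 and 0.126 (limma).

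The mock-higher spot B24_R2_C28 (block 24, row 2, column 28), chosen after its values were seen, had a log2 ratio of -0.62 (SE 0.033; limma, adjusted p = 0.0066). It was mock-higher on 3 of 6 arrays. Those were replicates 1, 3 and 5, with log2 ratios of -1.16, -1.40 and -1.29. On replicates 2, 4 and 6, where the dyes were exchanged, the ratios were 0.02, 0.01 and 0.08. The fitted value is therefore the midpoint of 2 orientations that differed, and on the Orb-in-Cy5 arrays alone it turned to 0.038. With consecutive arrays averaged its adjusted p was 0.105 (limma), and under median centring its log2 ratio was -0.43 (SE 0.169; limma, adjusted p = 0.548).

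**Figure D3:**
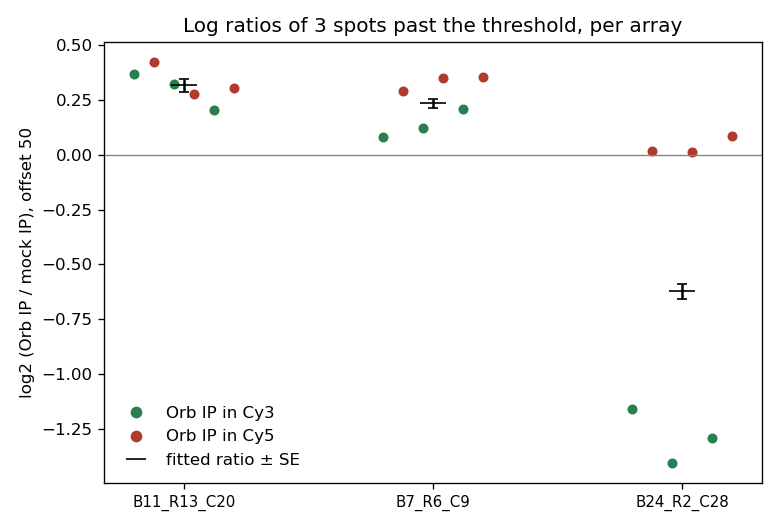
Points give the log2 ratio of Orb IP over mock IP (vertical axis, offset 50) of 3 spots on each of the 6 arrays, coloured by the dye of the Orb IP, with the fitted ratio and its SE as a bar. B11_R13_C20 and B7_R6_C9 lie above 0 on all arrays, and B24_R2_C28 lies between -1.40 and -1.16 with Orb in Cy3 and between 0.01 and 0.08 with Orb in Cy5.

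Within each orientation the outcome differed. On the 3 arrays with Orb in Cy3, 0 spots passed the threshold (limma), with 56 Orb-higher and 57 mock-higher spots at an unadjusted p under 0.05. On the 3 arrays with Orb in Cy5, 32 spots passed, all Orb-higher, with 561 Orb-higher and 3 mock-higher at an unadjusted p under 0.05. Of all tested spots, 90.3% had a mean ratio above 0 on those arrays, against 49.1% on the Orb-in-Cy3 arrays. The median log2 ratios of the tested spots were 0.040 and -0.0005. The direction of the called spots therefore does not set them apart from the tested spots. The difference between the 2 orientations is the dye term of the model and was not tested as a separate count. That term takes the dye bias of a spot to be the same on both sets of arrays, which was not tested. A bias that differed between the sets would enter the term for Orb over mock.

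Array-to-array agreement was low. Across the 2370 tested spots, the Spearman correlation of the Orb over mock ratios averaged 0.279 over the 6 pairs of arrays with the same dye orientation. It averaged 0.099 over the 9 pairs of opposite orientation, of which 4 were positive. The highest value was 0.677, between replicates 2 and 6, and the lowest was -0.090, between replicates 3 and 5. The mean ratios of the 2 orientations correlated at 0.192 (Spearman) and 0.117 (Pearson) across spots.

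A set of 28 spots was above background in both channels on all 6 arrays. Within these, 1 was Orb-higher and 1 mock-higher at an unadjusted p under 0.05, too few to show a direction. The mock-higher one, B24_R4_C27 (block 24, row 4, column 27), chosen after its values were seen, had a log2 ratio of -0.65 (SE 0.156; limma, adjusted p = 0.0226 over the 28 spots) and was mock-higher on 6 of 6 arrays after normalization. Before normalization its signal over background was 287 ± 158 units in the Orb IP and 278 ± 265 in the mock IP (SD, n = 6), and the mock signal was the higher one on 3 of the arrays. Over all tested spots its adjusted p was 0.118. Its log2 ratios ranged from -1.66 on replicate 1 to -0.11 on replicate 6.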

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

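The offset of 1, both changes to the repeated prints, the kept flags, both fits with loess on the tested spots, the deposited ratio and the detection limits were chosen after seeing the data. Against 26 calls (25 Orb-higher) in 2370 spots, limma gave 0 calls in 12 of 31 alternatives. These were no background correction, plain subtraction, median centring, print-tip loess, consecutive arrays averaged, the Orb-in-Cy3 arrays alone, a minimum log2 ratio of 0.5, the unmoderated t-test, loess on tested spots without background correction, the authors' deposited ratio, and leaving out replicate 2 or replicate 6. At an unadjusted p under 0.05 they gave Orb-higher and mock-higher spots, in that order, of 156 and 89, 151 and 21, 152 and 52, 370 and 15, 355 and 13, 56 and 57, 0 and 2, 369 and 17, 97 and 152, 148 and 21, 359 and 6, and 368 and 7. The count was 1 (Orb-higher) without the dye term, 1 (0 Orb-higher) for spots above background in both channels on all arrays, and 1 (0 Orb-higher) with loess on the tested spots, where 155 and 93 had an unadjusted p under 0.05. It was 14 (13 Orb-higher) with repeated prints set by both channels and 41 (23 Orb-higher) with all of them kept. Higher counts came with an offset of 0 (110, of which 108 Orb-higher), an offset of 1 (76, of which 74), scaling between arrays (90, of which 88), array weights (163, of which 161) and trended robust moderation (50, all Orb-higher). Leaving out 1 array gave 0 to 54 calls (0 to 52 Orb-higher), with 2 without replicate 1, 26 without replicate 3, 54 without replicate 4 and 15 without replicate 5. Taking consecutive arrays as a block gave 23, Aquantile 26, no filter 18, the Orb-in-Cy5 arrays alone 32 and kept flags 29. The causes of these shifts were not tested, beyond the simulated sets. There, median centring and fits without background correction called a median of 0. So did the planned normexp and loess without the dye term. Normexp with loess and the dye term called a median of 677, or 418 with an offset of 1 and 170 with loess on the tested spots. Orb-higher spots outnumbered mock-higher ones at an unadjusted p under 0.05 in 27 of 31 alternatives. The exceptions were the Orb-in-Cy3 arrays alone, the minimum size, spots in both channels on all arrays, and loess on tested spots without background correction. The minimum log2 ratio of 0.5 lay above the highest ratio of the 25 Orb-higher calls (0.32 with the offset of 50). That setting could therefore call none of them, and its counts do not bear on their stability.

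For the 13 spots past the threshold that were followed, 158 of 390 values stayed past it with the same sign. B24_R2_C28 turned to 0.038 on the Orb-in-Cy5 arrays alone; the other 12 spots had been chosen for 1 sign on all 6 arrays, so their signs say little about stability. Spots above background on all 6 arrays in the mock IP fell from 31 to 8 at 3 SD and to 10 at 10 units; in the Orb IP they numbered 153 at 10 units, against 435. Leaving out 1 array gave 436 to 585 in the Orb IP and 31 to 114 in the mock IP, with 114 without replicate 4. Deviations of consecutive arrays correlated (Pearson, across spots) at 0.184, 0.345 and 0.247, and those of other pairs of opposite dye at -0.294 to 0.194. By Spearman the consecutive arrays gave 0.099, 0.219 and 0.107, and the other pairs -0.224 to 0.179. The correlation within consecutive arrays fitted for the block was -0.076, so that fit did not model a positive pairing. Neither these values nor the labels settle whether the arrays were paired. The ratios of orb and Atg12, the gene lists, the mean over probes of a gene and the set tests were not run, since spots carry no gene names. Signal over background is a limit, as are the unequal channel noise and the possible pairing of arrays: 15.4% of spots were bright enough to be tested, and simulated changes of a log2 of 1 were recovered by median centring in 4 of 100 spots.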

Other observations

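Except for the reading of one set of arrays on the other as a whole, the tests below, that reading's single-array, median-centred and simulated versions included, were chosen after the results they measure had been seen.

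Nearly all spots past the threshold were Orb-higher (25 of 26). Unequal noise or gain of the channels is a candidate explanation. Noise in the Orb channel was 0.109 to 0.282 units with Orb in Cy5, against 3.65 to 4.62 in the mock channel. Gain there was 0.742 to 1.02 in the Orb channel and 0.0804 to 0.219 in the mock channel. Simulated arrays with such channels and no difference between the IPs gave a median of 670.5 Orb-higher calls (601 to 696 in 20 sets). These were more than on the real arrays, so they show the direction of a bias and not its size. Noise and gain were not varied separately, so the simulated sets cannot tell which of them gave it. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05; 1 of the 10, the real one, gave as many calls, with 26 against 0 in the highest other. Of 32 exchanges of the IPs within arrays, in the fit without a dye term, 2 gave as many calls (1, the real one included) and 3 gave as many spots at an unadjusted p under 0.05 (309, with 444 in the highest other).

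Spots picked as Orb-higher on the Orb-in-Cy5 arrays (561, unadjusted p under 0.05) were Orb-higher on the Orb-in-Cy3 arrays in 59.4% of cases, against 54.8% for spots of like brightness, an excess of 4.54 points and above the central 95% of 10000 matched draws (51.7% to 57.8%). The reverse reading of 56 spots gave 98.2% (matched draws 82.1% to 96.4%), and 20 simulated unchanged sets gave -1.94 to 0.05 points. A spot-specific dye bias alone would put the excess at 0 or below, as was written down before the test, but that bound came from draws of spots and took no account of the spread between arrays. Read singly, replicate 1 gave 72.9% (draws 60.2% to 66.1%, excess 9.78 points). Replicate 3 gave 52.5% (49.6% to 55.7%, -0.158) and replicate 5 gave 43.0% (36.2% to 42.1%, 3.89). The excess was 8.62 points without replicate 3 and 5.50 without replicate 5, both above the draws. Without replicate 1 it was 1.11 points, within the draws. Under median centring, which picked 201 spots, it was 1.85 points, within the draws. With median centring and no replicate 1 it was -5.26 points. A dye bias of the Orb-in-Cy5 arrays, where Cy3 was weak, therefore stays open. Replicate 3, with Orb in Cy3, also had a lower gain in Cy3 than in Cy5 (0.417 against 1.32). Binding of RNA by Orb, the biological explanation that the design names, was not tested, since that would need gene names for the spots.

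In the fit without a dye term, turning the sign of replicate 5 raised the spots with an unadjusted p under 0.05 from 309 to 444. Across the tested spots its Spearman correlations with the other arrays averaged -0.017, but its Pearson correlations were all positive, at 0.023 to 0.353. Replicate 3 had Pearson correlations of -0.203 with replicate 2 and -0.249 with replicate 6, and positive ones with the others. If the dyes of replicate 5 had been exchanged, its correlations with the other arrays, as labelled, would be below 0 among dim and bright spots alike. Among the brightest 25% of tested spots the Spearman correlation averaged 0.156 ± 0.212 (SD over the other 5 arrays), with 0.369, 0.265, -0.173, 0.075 and 0.246 for replicates 1, 2, 3, 4 and 6, so the arrays do not decide this. Signal near background stays open too: the mean was higher by 0.201 in the brightest than in the dimmest 25%, but the order from dim to bright was -0.045, -0.084, -0.075 and 0.156, and the difference was below 0 with replicate 3 (-0.119). No biological explanation was tested for this array.

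The repeated prints in the first row of the blocks were brighter in Cy5 at 9, 13, 13, 11, 10 and 13 of 13 positions on replicates 1 to 6. Their median log2 ratio of Orb over mock was -0.079, 3.71, -2.14, 1.09, -0.134 and 2.43 on replicates 1 to 6.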
